A study of Homo sapiens with 10 samples.

How the data were processed

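Total RNA was measured by RNA sequencing in 10 libraries from a mouse model of pancreatic cancer built with SW1990, an established human pancreatic adenocarcinoma cell line. Ribosomal RNA was depleted and directional libraries were made, per the labels' protocols. The labels put 5 libraries in a QYHJ group and 5 in a control group. Replicates are numbered from 1 to 5 within each group as names only, and the numbers pair no libraries. The dose, the duration and the tissue site are not given in the sources used here, and neither is whether the libraries came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

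The deposited values are whole-number counts per gene, not scaled between libraries. HISAT2, StringTie and the hg38 build are named without versions in the submitters' processing notes. The annotation release, the strand setting, the way counts were made from the StringTie output and the handling of reads from mouse cells are not given in the sources used here. The table held 60656 gene rows named by symbol, of which 1166 shared 119 repeated names and were kept as separate rows. Counts of genes that overlap other genes, lie antisense to them or have near-identical copies are uncertain, because the split of their reads depends on that counting. Library totals ran from 42610610 to 123279271 counts. No pair of libraries agreed within sampling noise (chi-square per degree of freedom from 65.7 to 474 over pairs), so all 10 were kept as separate samples. The number of per-sample columns left unused was 0.

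Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 21916 genes. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with robust dispersion estimates and group as the only term. Benjamini-Hochberg adjustment was used over all genes tested, with a threshold of 0.05. Values per gene are TMM-scaled CPM (counts scaled to a common library size), and shares of a library use its deposited total count. Confidence intervals are at 95%. All tests are 2-sided. Where every library of a group had 0 counts, the fold is a bound against a floor of 3 counts per library. The intervals come from the standard errors of the edgeR fit, and so from the spread between libraries, while the floor covers counting error only.

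A total of 42 gene lists was fixed before the data were examined, holding 1063 different symbols, of which 1057 were found (25 through an older symbol). The 41 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. Camera with an estimated correlation, the rotation test fry, and an exact permutation of the group labels on the mean log2 CPM of each list (prior count 2) were run beside it. The erythroid and platelet marker list had only 3 tested members and was not tested.

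Named genes were chosen by a rule fixed before the data were examined. It took 8 genes per direction with a mean CPM of at least 1, those past the threshold first by fold change and then those of smallest unadjusted p. It also took the 3 members of smallest p from each list that passed camera or held a member past the threshold, for at most 12 lists, and 14 genes fixed by name. A few genes that this rule names are not reported here. Features named outside this rule are said to be chosen after their values were seen. Coordinates are from GENCODE release 29 on GRCh38, the assembly that hg38 names, where 54865 rows had a unique match by name. No coordinates are given for rows whose names had no match there.

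The procedure was tested on counts simulated from these libraries' means, sizes and dispersions for the comparison of QYHJ with control, over 20676 genes. It called 32% of 100 genes changed 2-fold and 75% of 100 genes changed 4-fold, and 1 of 20476 unchanged genes. A list shifted by 0.5 on the log2 scale was called with a median of 0.50, together with 1 of the other lists. Genes were simulated independently, so this did not test list calls under correlation between genes. The shifted list, of the hypoxia response, had an estimated correlation of 0.30 in the real libraries.

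Alternatives fixed before the data were examined were upper-quartile factors, DESeq2 size factors in edgeR, DESeq2 1.42.0, limma voom with sample quality weights, no filter on low counts, a mean count of at least 50, an adjusted p under 0.10, an unadjusted p under 0.05 with an absolute log2 fold change of at least 1, the final letter of the library title as a term, the number in the library title as a replicate block, library sizes without structured, mitochondrial and clone-named genes, and leaving out each library. A class of each library by its RPPH1 count, fits within each class, a correction for GC content and the exact permutation test of lists were added after seeing the data.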

Results

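Gene expression was measured in 10 libraries of SW1990 pancreatic cancer cells grown in mice, 5 labelled as treated with QYHJ and 5 as controls. Deposited gene counts totalled 68249206 to 113753895 per QYHJ library and 42610610 to 123279271 per control library. The comparison asked which genes and gene groups differed between QYHJ and control.

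No single gene passed the threshold with QYHJ. Among the 11 gene lists called when a preset correlation between genes was used, those of DNA replication and cell division lay higher and those of ribosomal proteins and hypoxia lay lower, but with a correlation estimated from the data 0 of 41 lists passed (smallest adjusted p = 0.84 with an estimated correlation). Of 33 genes of G1/S and DNA replication, 32 had a positive log2 fold change, with a median of 0.39. Of 32 genes of the hypoxia response, 29 had a negative one, with a median of -0.28. edgeR's quasi-likelihood test called 0 of 21916 genes at an adjusted p under 0.05, where 561 had an unadjusted p under 0.05 and 1096 were expected by chance. DESeq2 called 3 genes, all lower, and limma voom with quality weights called 0. The smallest adjusted p in edgeR was 0.569.

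Among the 8 highest ranked genes with larger values in QYHJ, none passed the adjusted threshold (adjusted p = 0.9999 in edgeR for each). TXNRD1, the cytosolic thioredoxin reductase (chromosome 12, 104215779 to 104350305, GRCh38), had 95.1 ± 13.4 CPM with QYHJ and 65.6 ± 7.40 in controls (SD, n = 5 each). Its log2 fold change was 0.54 ± 0.14 (SE), and all 5 QYHJ libraries lay above every control. BRCA2, a protein of homologous recombination repair (chromosome 13, 32315474 to 32400266), had 71.9 ± 19.1 against 41.6 ± 7.70 CPM, a log2 fold change of 0.79 ± 0.21. WDHD1, which takes part in DNA replication (chromosome 14, 54938950 to 55027105), had a log2 fold change of 0.64 ± 0.18. HIVEP1, a zinc finger transcription factor gene, had 0.58 ± 0.16. MARCHF4, a membrane-bound ubiquitin ligase, had 9.37 ± 3.33 against 3.29 ± 1.73 CPM, a log2 fold change of 1.52 ± 0.37. PALM2AKAP2, which overlaps the genes it joins and is uncertain for that reason, had 1.07 ± 0.26. PPAN, a ribosome biogenesis factor (chromosome 19, 10106289 to 10111634), had 1.68 ± 0.40 but shares its exons with the readthrough gene PPAN-P2RY11. The counts of both together differed by 0.17 on the log2 scale (exact permutation p = 0.627), with 10.9 ± 5.27 CPM with QYHJ and 9.07 ± 2.14 in controls.

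Among the 8 highest ranked genes with smaller values in QYHJ, B3GAT2, a glucuronyltransferase gene (chromosome 6, 70856679 to 70957038), had 0.733 ± 0.232 CPM with QYHJ and 6.45 ± 3.71 in controls, a log2 fold change of -3.13 ± 0.52 (edgeR adjusted p = 0.569). AC013477.2, a clone-named row, had 0 counts in the 5 QYHJ libraries and 15 to 282 in the 5 controls, at least 60.8-fold lower against a floor of 3 counts per library (edgeR adjusted p = 0.569). Without control replicate 2, the highest control, the bound was 39.7-fold, and control replicate 1 had 0.152 CPM against a mean of 2.07 ± 1.83 in controls. CP, which encodes the copper-carrying ferroxidase ceruloplasmin (chromosome 3, 149162410 to 149222055), had 38.2 ± 7.07 against 78.7 ± 20.5 CPM, a log2 fold change of -1.04 ± 0.20 (edgeR adjusted p = 0.9999). All 5 QYHJ libraries lay below every control for these 3 genes, and they were the 3 genes that DESeq2 called, with adjusted p of 4.45e-06, 1.50e-10 and 0.0093 in the order given. B3GAT2 also passed in edgeR without control replicate 1, with an adjusted p of 0.0318. That library held the lowest control value of B3GAT2, 1.20 CPM, near the highest QYHJ value of 0.903, while the other controls had 4.87 to 11.1. Leaving out the control nearest to QYHJ is no added support. The coactivator gene PNRC1 and the transcription factor gene MAF had log2 fold changes of -0.50 ± 0.13 and -0.72 ± 0.20, and FAM83F had -0.86 ± 0.25. PCDHGA10 had -0.76 ± 0.22 and is uncertain, since genes of its protocadherin cluster share exons. TF, the transferrin gene, had -2.44 ± 0.72, and the value without control replicate 2 was -1.30. Within the low and the high class of library described at the end, log2 fold changes were 0.68 and 0.32 for TXNRD1, -2.61 and -3.63 for B3GAT2 and -1.03 and -1.05 for CP, which is no separate evidence, since the genes were chosen on the same libraries. Over all genes, the groups did not overlap for 108 genes, 0.493% of those tested, where chance gives 0.794%.

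**Figure D1:**
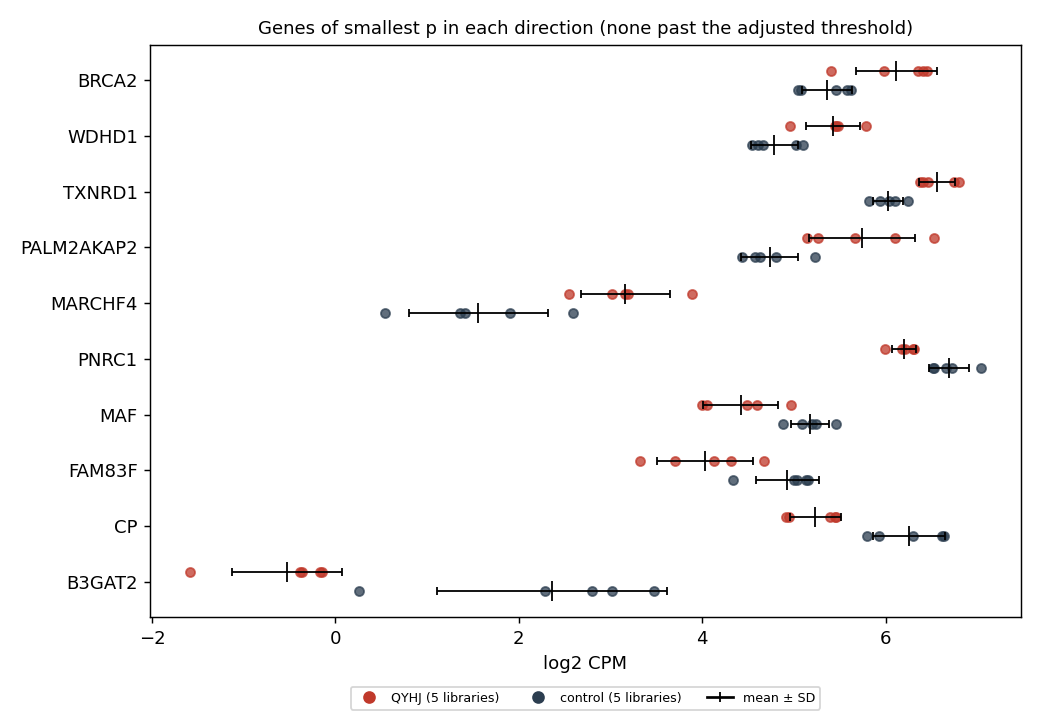
The plot shows log2 CPM of 10 of the 16 genes named by rank, with a point per library (red, QYHJ; dark, control) and bars for the mean ± SD of 5 libraries on the log2 scale. For TXNRD1, PNRC1, CP and B3GAT2 the groups did not overlap, and no gene passed the adjusted threshold in edgeR.

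With the preset correlation of 0.01, camera called 11 of the 41 lists, 5 higher and 6 lower with QYHJ, and no member of any list passed the threshold over all genes. The adjusted p of these 11 lists was 0.84 to 0.927 with an estimated correlation, so none held. Fry also called 0 lists (smallest adjusted p = 0.776). The exact permutation of list scores called 0 as well. It had little power after adjustment, since its smallest possible p was 0.00794 and at least 7 of the 41 lists would have had to reach it. No list did so: the smallest unadjusted exact permutation p was 0.0317, for glycolysis, and 2 lists were under 0.05. The G1/S list had 0.0873 and interferon-stimulated genes 0.524 in that test. The G1/S list had 33 tested members (camera adjusted p = 2.02e-16, and 0.84 with an estimated correlation). Of these, 0 were past the threshold adjusted over the list alone and 7 had an unadjusted p under 0.05. MCM4 and MCM6, parts of the replicative helicase, had log2 fold changes of 0.52 ± 0.17 and 0.65 ± 0.23, and the clamp loader gene RFC3 had 0.55 ± 0.20. In the G2/M and mitosis list, 32 of 34 members were positive, with a median of 0.23 (camera adjusted p = 2.03e-08; adjusted p = 0.84 with an estimated correlation). The spindle checkpoint kinase gene BUB1 had 0.46 ± 0.17 there, the spindle assembly gene TPX2 0.46 ± 0.20 and the proliferation marker MKI67 0.39 ± 0.22 (0.24 without control replicate 2). The G2/M median was 0.13 without control replicate 2 and 0.14 without QYHJ replicate 1. Of 30 MYC targets and ribosome biogenesis genes, 24 were positive, with a median of 0.19 (camera adjusted p = 8.65e-07; adjusted p = 0.84 with an estimated correlation). PPAN, the uncertain gene above, was the 1 member past the threshold adjusted over the list alone. UTP20, of the small subunit processome, had 0.48 ± 0.16 and POLR1A, of RNA polymerase I, 0.36 ± 0.16.

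Interferon-stimulated genes had 35 of 40 positive members and a median of 0.27 (camera adjusted p = 2.83e-05; adjusted p = 0.927 with an estimated correlation), but single members varied widely. DDX58, which encodes the RNA sensor RIG-I, had 70.5 ± 38.6 CPM with QYHJ and 42.6 ± 26.2 in controls, a log2 fold change of 0.73 ± 0.43. OASL and IFIH1, another sensor gene, had 0.79 ± 0.59 and 0.49 ± 0.41. Without control replicate 1 DDX58, OASL and IFIH1 had 1.17, 1.47 and 0.96. Without QYHJ replicate 4 DDX58 and OASL had 0.43 and 0.23, and IFIH1 had 0.24 without QYHJ replicate 2 and 0.31 without control replicate 4. The call was lost without QYHJ replicate 4 (median 0.068) or control replicate 2 (0.13), and with the title letter as a term (0.047). With the title number as a replicate block over 4 libraries the list was called lower (-0.42). The median was 0.55 without control replicate 1, 0.42 without QYHJ replicate 5, 0.15 without QYHJ replicate 2 and 0.14 without control replicate 4. The heat shock list had 16 of 21 positive members and a median of 0.21 (camera adjusted p = 0.0195; adjusted p = 0.927 with an estimated correlation). The chaperone genes HSP90AA1 and HSPA8 had 0.27 ± 0.13 and 0.24 ± 0.14, and HSPB1 had -0.39 ± 0.27 (-0.22 without control replicate 3). The heat shock call was lost without QYHJ replicate 1 or 3 or control replicate 2, 4 or 5, with medians from 0.092 to 0.29 over the 10 libraries left out, and the median was 0.13 without QYHJ replicate 2.

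Of 73 cytoplasmic ribosomal protein genes, 72 had negative log2 fold changes, with a median of -0.26 (camera adjusted p = 9.76e-09; adjusted p = 0.84 with an estimated correlation). RPL35A, RPL23 and RPL39 had -0.39 ± 0.16, -0.33 ± 0.16 and -0.37 ± 0.18, and all are uncertain because their processed pseudogenes can share reads. The median of this list was -0.16 without QYHJ replicate 2. The hypoxia list had a camera adjusted p of 9.63e-06 (adjusted p = 0.84 with an estimated correlation). In it, PDK1, a kinase that inhibits pyruvate dehydrogenase, had -0.40 ± 0.18 (-0.23 without control replicate 5). The collagen prolyl hydroxylase gene P4HA2 had -0.36 ± 0.16 and the oxygen sensor gene EGLN1 had -0.25 ± 0.12. The hypoxia median was -0.16 without QYHJ replicate 1 and -0.19 without control replicate 4. Glycolysis genes were negative for 18 of 19 members, with a median of -0.13 (camera adjusted p = 0.0222; adjusted p = 0.927 with an estimated correlation), and PGK1, ALDOC and GAPDH had -0.38 ± 0.19, -0.41 ± 0.27 and -0.22 ± 0.19. ALDOC had -0.27 without control replicate 4, and GAPDH had -0.10 without control replicate 5, -0.13 without control replicate 1 and -0.14 without QYHJ replicate 2. A correction for GC content raised the median of all genes from -0.041 to 0.083. With it the medians went from -0.27 to -0.12 for ribosomal proteins, from -0.30 to -0.16 for hypoxia and from -0.16 to 0.043 for glycolysis, whose call was lost (camera adjusted p = 0.756). Measured from the median of all genes, these were 0.851, 0.921 and 0.345 times the values before. Circadian clock genes were negative for 16 of 19 members, with a median of -0.20 (camera adjusted p = 0.0257; adjusted p = 0.84 with an estimated correlation). Among them DBP had -0.88 ± 0.37 and PER1 -0.92 ± 0.49, or -0.48 without control replicate 5. For basal and squamous keratinization, 21 of 30 members were negative, with a median of -0.14 (camera adjusted p = 0.0218; adjusted p = 0.927 with an estimated correlation). KRT17 had 584 ± 254 CPM with QYHJ and 865 ± 264 in controls, KRT81 had a log2 fold change of -0.74 ± 0.38 (-0.31 without control replicate 1) and S100A7 had -1.55 ± 0.78 (1.55 times smaller without control replicate 1). Members of the p53 list were negative for 23 of 28 genes, with a median of -0.25 (camera adjusted p = 0.0456; adjusted p = 0.927 with an estimated correlation). SPATA18 had -0.56 ± 0.28, and -0.34 without control replicate 5. RRM2B and ZMAT3 had -0.81 ± 0.44 and -0.92 ± 0.50, values that rested on control replicate 5: without it they were -0.065 and -0.042, and the list's median was -0.016. The p53 call was also lost without QYHJ replicate 2, 3 or 5 or control replicate 1 (medians -0.25, -0.19, -0.21 and -0.30). The keratinization call was lost without QYHJ replicate 1 or 3 or control replicate 1, 3, 4 or 5 (medians -0.16 to -0.087). It was kept without QYHJ replicate 2, 4 or 5 or control replicate 2 (-0.24, -0.30, -0.21 and -0.22). The glycolysis call was lost without QYHJ replicate 1 or 2 or control replicate 1, 3, 4 or 5 (-0.14 to -0.045). It was kept without QYHJ replicate 3 (-0.19) and without QYHJ replicate 4 or 5 or control replicate 2 (-0.23 each). The circadian call was lost without QYHJ replicate 1 or 4 or control replicate 4 or 5 (-0.20 to -0.091). In the other circadian fits it was kept (-0.25 to -0.16).

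**Figure D2:**
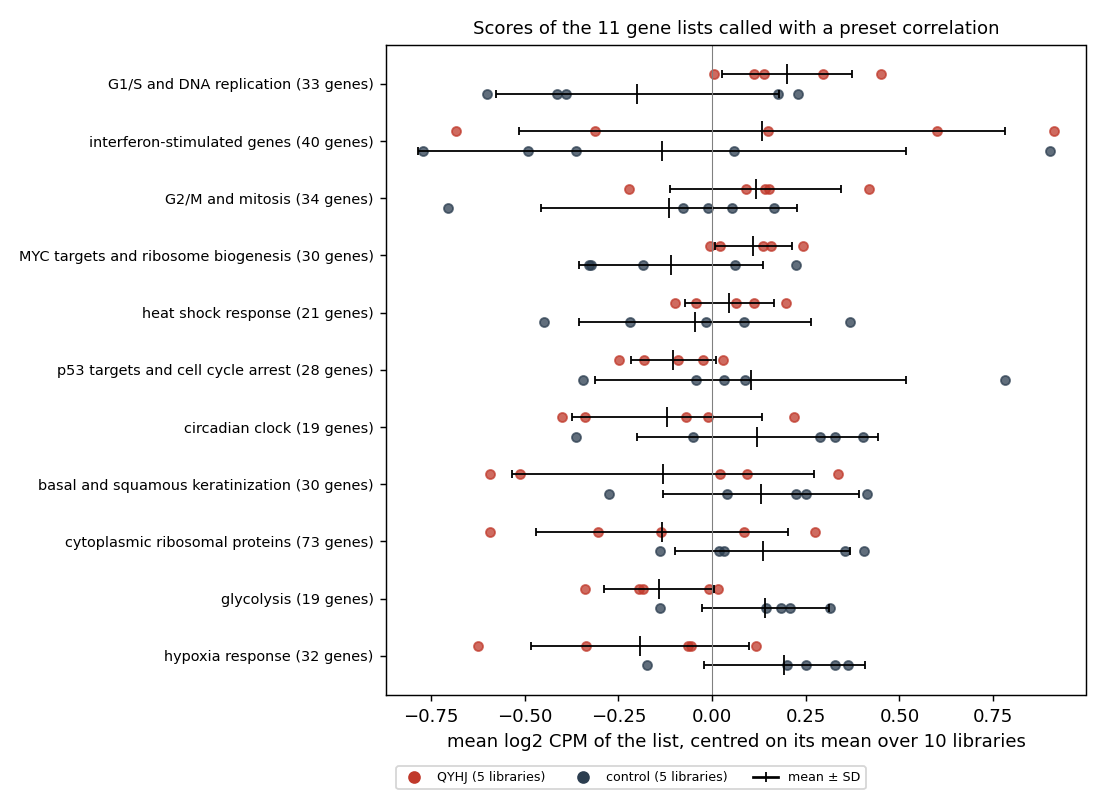
The plot shows the mean log2 CPM of each of the 11 lists called with the preset correlation, centred on its mean over the 10 libraries, with a point per library and bars for the mean ± SD of 5 libraries. The groups overlapped in every list shown, and with an estimated correlation 0 of the lists passed (smallest adjusted p = 0.84).

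Markers of pancreatic cancer cells and of the pathways fixed by name did not pass in edgeR (adjusted p = 0.9999 for each tested gene). SMAD4 had 40.1 ± 1.77 CPM with QYHJ and 39.6 ± 2.73 in controls, a log2 fold change with a 95% confidence interval of -0.21 to 0.25. The ductal keratin gene KRT19 had a log2 fold change of -0.31 ± 0.18 (-0.19 without control replicate 5), EPCAM 0.19 ± 0.15 (0.12 without QYHJ replicate 3, 0.29 without control replicate 1), VIM 0.16 ± 0.25 and MYC 0.12 ± 0.21. The Notch targets HES1 and HEY1 had 0.13 ± 0.28 and 0.67 ± 0.69, and HEY1 had 0.35 without QYHJ replicate 4, 0.41 without control replicate 2 and 1.32 without control replicate 3. HMOX1, the heme oxygenase gene, had 0.87 ± 0.47 (0.38 without QYHJ replicate 4), and the ferroptosis regulators GPX4 and SLC7A11 had -0.28 ± 0.16 (-0.15 without control replicate 5) and 0.01 ± 0.21. CDKN1A had 105 ± 8.64 CPM with QYHJ and 153 ± 110 in controls, a log2 fold change of -0.55 ± 0.34, and 0.01 without control replicate 5. CYP1A1 was below the count filter, with at most 71 counts in a library.

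Markers of other cell types were measured beside these groups. These are human gene rows, and the handling of mouse reads is not given, so the lists do not measure host tissue. Whether their counts came from the cancer cells or from other cells was not tested. Mean log2 CPM was low for the leukocyte list (0.83 with QYHJ, 1.23 in controls) and the endothelial list (0.63 and 0.80). The fibroblast and matrix list had a median of -0.18 over 24 genes (camera adjusted p = 0.196), the leukocyte and macrophage list -0.38 over 16 genes (0.386), the endothelial list -0.19 over 10 genes (0.916) and the epithelial and ductal list -0.14 over 32 genes (0.169). Without control replicate 2 these medians were 0.060, 0.022, 0.35 and -0.095. The epithelial median was also -0.037 without control replicate 4, -0.075 without QYHJ replicate 1 and 0.044 after GC correction. In the other direction it was -0.23 without QYHJ replicate 4, -0.26 without QYHJ replicate 5 and -0.25 without control replicate 1. The fibroblast list was called lower without QYHJ replicate 1 (-0.49, camera adjusted p = 0.00645), QYHJ replicate 3 (0.0480) or control replicate 3 (0.0316), and within the high RPPH1 class (-0.47, 0.0083). The epithelial list was called lower without QYHJ replicate 2 (camera adjusted p = 0.0334), control replicate 1 (0.00311) or control replicate 2 (0.0196), in limma voom (0.0157), within the high class (1.72e-08) and with the class as a term and control replicate 2 left out (0.0403). No estimated correlation was run for these alternatives. Exocrine pancreas and liver markers had a median of -0.02 over 18 genes (camera adjusted p = 0.914), with 2 members past the threshold adjusted over the list alone and 0 over all genes. These were TF, above, and the apolipoprotein gene APOA1, with 22 to 70 counts in the QYHJ libraries, 4 counts in control replicate 4 and 0 in the other controls. Without QYHJ replicate 5 the exocrine list was called lower, with a median of -0.99 (camera adjusted p = 0.024), and without control replicate 3 the median was 0.81. As a difference of mean log2 CPM the exocrine median was -0.74, and -0.59 after GC correction (camera adjusted p = 0.494). ALB, the albumin gene, had a log2 fold change of -4.08 ± 1.47, and -1.02 without control replicate 2. Not called either were the lists of small structured RNAs, nuclear oxidative phosphorylation, cholesterol synthesis, stem cell markers, mesenchymal markers, MHC class I antigen presentation, skeletal muscle markers, ER stress, JAK-STAT3 targets, TGF-beta targets, the Notch, Wnt and Hedgehog pathways, immediate early genes, apoptosis regulators, mitochondrially encoded genes, angiogenic factors, NRF2 targets and ferroptosis, NF-kB inflammatory genes, nuclear long noncoding RNAs, xenobiotic metabolism, autophagy, lipid metabolism, replication-dependent histones, and adipocyte and skin markers. Their camera adjusted p ran from 0.0838 to 0.977. In 11 of the 41 lists, none of them called, the median had the other sign than the test.

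The libraries were also put into 2 classes at the largest gap in the log2 CPM of RPPH1, the RNA of ribonuclease P. QYHJ replicates 4 and 5 and control replicates 3 and 4 had 6256 to 10275 CPM of RPPH1, and the other 6 libraries had 1932 to 3307. The class split each group, with 2 QYHJ and 2 control libraries in the high class and 3 of each in the low class. Within the low class edgeR called 0 genes, and within the high class it called 1, PIK3R2, named after its values were seen. The G1/S median was 0.48 within the low class and 0.25 within the high class, and the hypoxia median was -0.40 and -0.17. MYC targets had 0.14 and 0.28 and interferon-stimulated genes 0.14 and 0.47. Ribosomal proteins had -0.43 and -0.02, G2/M genes 0.33 and 0.05, glycolysis -0.31 and -0.03, heat shock genes 0.25 and 0.09, keratinization -0.21 and -0.11 and p53 targets -0.47 and -0.04, and these 6 lists were called by camera in the low class only, a difference that was not tested. These calls within classes used the preset correlation, and no estimated correlation was run there. Circadian clock genes had -0.15 and -0.13 and were called in neither class. Control replicate 2 stood apart in another way, with the lowest total but 39373 genes with at least 1 count against 24151 to 33537 in the others. The first principal component, 28.4% of the variance, set it apart, and its median correlation with the other libraries was 0.837. Without it edgeR still called 0 genes, and camera called 16 lists with the preset correlation, 9 of them among the 11.

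**Figure D3:**
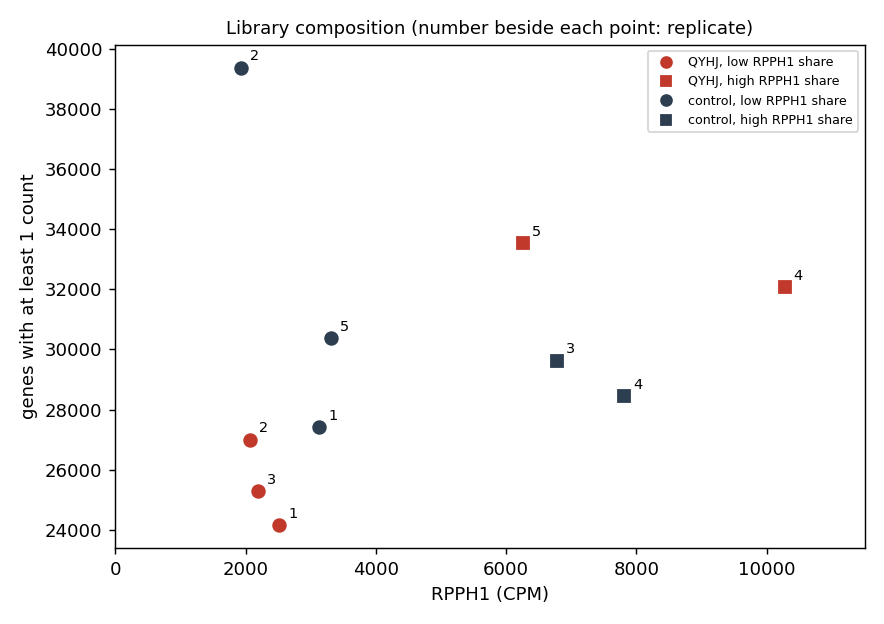
The plot shows, for each of the 10 libraries, the CPM of RPPH1 (horizontal axis) against the number of genes with at least 1 count (vertical axis, not starting at 0). Squares mark the 4 libraries of the high RPPH1 class, 2 from each group, and control replicate 2 lies at the top with 39373 genes.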

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

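The tests of another cell type, of the treatment as the source of the library classes and of control replicate 2 as the source of the G1/S shift were chosen only after the result was seen. A value was singled out when it lay far from the other libraries of its group, judged by its gap to the nearest one over the group's range. This happened for 17 of 163 groups of 5 values, where 1 in 20 would be about 8.15. That rate holds only for normally distributed values. The values here were not shown to be normal or independent, and many of the genes were chosen by p on these libraries. No excess over chance is therefore claimed.

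Control replicate 2 held 6 of them. It had 39373 genes with at least 1 count, 0.583% of counts in genes annotated as antisense (0.246 to 0.280% in the other controls) and 0.734% in mitochondrial ribosomal RNA (0.0115 to 0.0563%). Its G2/M list score was -0.71 against -0.08 to 0.16, and it had 9.22 CPM of TF (0.429 to 1.91) and 10.96 CPM of ALB (0.132 to 0.714). For RNA from another cell type as the source of the extra genes, 48.5% of 101 fixed markers of other tissues were highest in this library. That was 1.08 times the 44.9% of protein-coding genes matched on level (95% range of 1000 draws, 36.6 to 53.5%), below the bound set for this source. The test cannot decide, since genes matched on a low level in the other libraries could be raised by such RNA as well. This source stays open. A first test on the 7 markers with 0 counts in the other 9 libraries decided nothing and was replaced, since their median count was 0. Genomic DNA stays open: over 13602 genes with 0 counts in the other 9 libraries, the count rose with exonic length with a Spearman rho of 0.216 across genes, between the bounds set for and against it, and genes are not independent replicates. No other biological explanation was tested.

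The 4 libraries with a high RPPH1 count differed from the other 6 in 2724 of 21916 genes in edgeR with group as a term (adjusted p under 0.05), 1784 higher and 940 lower. The classes were cut at the largest gap of RPPH1 in these same counts, a rule that always gives 2 classes. The p-values between the classes therefore describe the split and are no independent test of it. Camera with the preset correlation called 6 lists between the classes, with median log2 differences, high minus low, of 0.36 for ribosomal proteins (adjusted p = 0.000827), 0.33 for glycolysis (0.0303), 0.32 for hypoxia (0.0477), 0.64 for the Notch pathway (5.56e-05), -0.31 for mitochondrially encoded genes (0.00308) and -0.89 for fibroblast markers (0.0477). The medians of the first 3 were larger in size between the classes than with QYHJ, a difference that was not tested. With the class as a term these 3 lists were still called for QYHJ (medians -0.27, -0.17 and -0.30). No estimated correlation was run for either. The treatment is argued against, since 2 of the 4 were QYHJ libraries. A trend with transcript length in a single direction is argued against too, with a Spearman rho of -0.0777 across genes between exonic length and the class difference. That rho could not show a dependence on length that goes in both directions. GC content stays open as a partial source, with a rho of 0.342 over the 20728 genes with a value. Single genes such as RPL31, at 485 CPM in the high class and 87.1 in the low class, and NAA10, at 7.13 and 38.8, were named after their values were seen. So were RPL29, at 942.5 and 188.3 CPM, and RPL38, at 42.87 and 160.7, which show that ribosomal protein genes went in both directions between the classes. A difference between library batches may be another source, but the labels used here name no batch. The number in the library title followed the classes, though. The high class held consecutive numbers, with those of the low class below and above them. The labels do not say what that number marks, so a batch stays open, and no other biological explanation was tested.

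The G1/S list lay higher with QYHJ, with a camera p that 6 of 100 splits of the 10 libraries reached (the real split included; smallest of the other splits, 6.08e-21), so chance was not excluded. Its median over the 33 genes was 0.39, and the highest of the other splits was 0.47. A GC difference between libraries is argued against as the whole source, since the median after correction was 1.502 times that before, or 1.159 times when measured from the median of all genes, which the correction raised. Control replicate 2 is argued against as well, since the median without it was 0.832 times that with it. Chance and an effect of QYHJ both stay open.

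The real split called 0 genes, which 100 of 100 splits reach by construction (highest other, 1405), so that count decides nothing. Of the splits, 74 gave at least its 561 genes at an unadjusted p under 0.05 (highest other, 4607). The split with 4607 genes put 5 libraries of the low RPPH1 class on 1 side, so it followed the library classes, and its count points to a structure of the samples. Of the 100 splits, 50 gave at least the 11 lists of the real split (highest other, 20), so chance was not excluded for the 561 genes or the 11 lists.

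Control replicate 5 had 345 CPM of CDKN1A (78.6 to 139 in the other controls), 222 of RRM2B (35.3 to 76.9) and 294 of ZMAT3 (35.7 to 87.5), and 53.1 of HIVEP1 (68.0 to 73.4). Control replicate 1 had 32.7 CPM of OASL (5.90 to 10.9), 86.6 of IFIH1 (19.4 to 35.4) and 20.1 of FAM83F (32.0 to 35.7). Control replicate 4 had 0.0399 CPM of APOA1 where the other controls had 0. Among QYHJ libraries, replicate 3 had 2.01 CPM of PPAN (6.64 to 8.40), and replicate 1 had 0.333 of B3GAT2 (0.765 to 0.903) and 37.1 of SMAD4 (40.4 to 41.5).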

How the results depend on the processing

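The library class, GC correction and exact permutation alternatives were chosen after seeing the data. The count of genes changed was 0 in edgeR with other size factors, a mean count of at least 50, the title letter, reduced library sizes, the class term and an adjusted p under 0.10, and in limma voom. It was 2, both lower, with no filter on low counts, 3, all lower, in DESeq2, and 1, higher, within the high RPPH1 class. An unadjusted p under 0.05 with an absolute log2 fold change of at least 1 gave 246 genes, 39 higher and 207 lower. Leaving out 1 library gave 0 to 1 genes (0 to 1 lower, 0 to 0 higher), the 1 being B3GAT2 without control replicate 1. The lists called were 0 with an estimated correlation, 0 with fry, 0 with the exact permutation, 6 after GC correction and 17 with the class term and control replicate 2 left out. Leaving out 1 library gave 6 to 16 lists, with 7 without control replicate 4, 6 without control replicate 5 and 16 without control replicate 2. The G1/S, hypoxia and MYC lists were called under each of their 23 alternatives other than those 3 tests. The median over all genes was -0.05, and -0.36 with no filter. The cause of these differences was not tested, beyond the fewer samples of some fits.

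The number in the library title was held by both groups for 4 libraries only, and the labels do not say that it pairs them. The correlation of deviations was 0.0873 and 0.138 for the 2 pairs. With it as a replicate block edgeR called 0 genes and camera with the preset correlation 12 lists, 8 of them among the 11 and 7 of these in the same direction. No estimated correlation was run under the block. There the interferon list was called lower with a median of -0.42 (adjusted p = 5.85e-18), leukocyte markers -0.046 and endothelial markers 0.22, and the log2 fold changes were -0.31 for DDX58, -0.40 for OASL, -0.19 for IFIH1, 0.027 for ZMAT3, -0.036 for EPCAM, -0.20 for VIM, -0.089 for SMAD4 and -0.24 for SLC7A11.

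Of 1354 values of named genes under alternatives, 1320 kept their direction and side of the threshold, 6 passed it and 28 changed sign. Within the high RPPH1 class the G2/M list was called neither way (median 0.047, with the other direction against other genes), and log2 fold changes were -0.023 for MKI67, 0.061 for S100A7, 0.092 for KRT81 and 0.11 for CDKN1A. Within the low class they were -0.17 for MYC, -0.0059 for SMAD4 and -0.17 for SLC7A11, and the epithelial list turned direction against other genes with a median of -0.079. With the title letter as a term, endothelial markers had -0.18 and SLC7A11 -0.056. Endothelial markers had 0.32 with the class term and control replicate 2 left out. SLC7A11 had -0.021 with upper-quartile factors, -0.000854 with a mean count of at least 50 and -0.00258 with the class term, and HES1 had -0.014 in limma voom. After GC correction the glycolysis median was 0.04. Leaving out 1 library gave -0.11 to 0.31 for VIM, -0.0062 to 0.26 for MYC, -0.0059 to 0.33 for HES1, -0.18 to 0.12 for SLC7A11, -0.70 to 0.0065 for CDKN1A, -0.34 to -0.016 for the p53 list, -0.99 to 0.81 for exocrine markers and -0.56 to 0.35 for endothelial markers.

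Of the 286 values of the called lists, 201 kept their call, 82 lost it and 3 changed direction. Apart from leaving out libraries, the classes and the 3 other list tests, calls were lost with no filter (keratinization, circadian, glycolysis, p53), after GC correction (those 4 and heat shock), under the block (G2/M, heat shock, p53), with the title letter (interferon) and with the class term and control replicate 2 left out (interferon, heat shock). Measured from the median of all genes, GC correction left the circadian median at 1.052 times its value before and heat shock at 1.045. It left p53 at 0.837, keratinization at 0.713 and glycolysis at 0.345. The median SE of a log2 fold change was 0.20 over the 8894 genes with a mean CPM of at least 10 and 0.26 over the 14989 with at least 1.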

Other observations

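Digestive enzyme genes of the exocrine pancreas varied between libraries far more than between groups, and the genes named here were chosen after their values were seen. Whether their counts came from the human cancer cells or from other tissue was not tested, and the handling of mouse reads is not given. CEL, which encodes the bile salt lipase, had 80.0 CPM in QYHJ replicate 5 and 67.5 in control replicate 3, 1.43 in QYHJ replicate 1 and 1.13 in control replicate 2, and 7.72 to 19.2 in the other 6 libraries. The procarboxypeptidase gene CPB1 was at 43.4 and 54.3 CPM in the first pair and 0.333 and 2.90 in the second. The pancreatic lipase gene PNLIP was at 29.4 and 26.9 in the first pair and 0 and 0.785 in the second. The score of the exocrine and liver list spanned 5.34 on the log2 scale, the widest of the lists tested (next, 2.53 for adipocyte and skin markers). Its spread within groups exceeded that of each of 1000 random lists of the same size matched on mean expression (percentile 100). That comparison is not particular to this list, since the interferon, G1/S, G2/M and ribosomal protein lists, among others, also reached percentile 100. CPA4, a carboxypeptidase gene of other tissues, stayed between 11.9 and 30.9 CPM in all 10 libraries.

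Interferon-stimulated genes also moved together within each group. Their centred list score was 0.91 in QYHJ replicate 4, 0.90 in control replicate 1 and 0.60 in QYHJ replicate 2, and -0.68 in QYHJ replicate 5 and -0.77 in control replicate 2. In control replicate 5, 19 of 28 members of the p53 list had their highest value of the 10 libraries. If each library were equally likely, that would be 2.8 members. This library was singled out after its values were seen, and the members are correlated (estimated correlation 0.35), so 2.8 is not a chance level here. The median of the members there was 0.76 higher on the log2 scale than in the other 9 libraries, and the list score was 0.78.

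The relations between list scores were stated before they were computed, and both form 1 family of 2 relations over 10 libraries. The hypothesis that hypoxia and G1/S scores move in opposite directions gave a Pearson r of -0.720 (permutation p = 0.0197, adjusted 0.0394) and a Spearman rho of -0.636 (permutation p = 0.0538, adjusted 0.108). Without control replicates 2 and 5, whose G1/S scores lay farthest from the median, r was -0.650. Within the 6 libraries of the low RPPH1 class r was -0.949, and the high class held too few for a value. Computed on deviations from the group means, r was -0.541. The permutation shuffled all 10 libraries across the groups, so its p also takes in the difference between the groups. No p was computed on the deviations. The relation may hold across these libraries, although the rank correlation did not pass after adjustment.

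The hypothesis that interferon-stimulated and MHC class I scores move in the same direction gave an r of 0.526 (permutation p = 0.120, adjusted 0.120) and a rho of 0.297 (permutation p = 0.406, adjusted 0.406), which did not pass. Without QYHJ replicate 4 and control replicate 1 r was 0.661, and within the 6 libraries of the low class it was 0.859. On deviations from the group means it was 0.678.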
